A study of Arabidopsis thaliana with 9 samples.

How the data were processed

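Small RNA was sequenced from inflorescences of Arabidopsis thaliana at floral stages 9 to 12, in 9 libraries of 6 genotypes. Per the labels, plants grew in long days without treatment, RNA was isolated with TRIzol from pooled tissue, and libraries were built with an Illumina TruSeq small RNA kit. The same protocol text also names NEBNext multiplex small RNA libraries, without saying which library came from which kit. The labels do not say whether libraries of one genotype came from separate plantings, so the p-values measure only the spread between these libraries, which may be technical.

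The deposited files list distinct small RNA sequences with their raw counts, and the values are counts in each of the 9 files with no normalization by the authors. Adapters had been removed and identical reads collapsed. The design text of the series names Illumina HiSeq sequencing, a read size of 18 to 26 nt and mapping with Bowtie; the Bowtie version and the authors' genome build are not given in the sources used here. Lengths were tested on the files. 4 libraries hold only reads of 18 to 26 nt, and the other libraries also hold shorter and longer reads, which were left out of the comparisons and are described in the closing section.

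Library titles fall into a pair of naming series. Series A comprises Col-0 replicate 1, ddm1-2 replicate 1, rdr6-15 and ddm1-2 rdr6-15. Series B comprises Col-0 replicate 2, ddm1-2 replicate 2 and both ddm1-2 dcl1-11 libraries. The construct library belongs to neither. Series A libraries hold 11236761 to 13096646 usable reads and series B libraries 241191 to 1707822, so that every rdr6-15 library is deep and every dcl1-11 library is shallow. The construct library has 179599 usable reads. Replicate numbers were assigned here, since the labels give none.

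Reads of 18 to 26 nt were matched to the TAIR10.1 assembly (nuclear, chloroplast and mitochondrial genomes) without mismatches by a hash search written in Python 3.11.15 with numpy 2.4.6, numba 0.67.0 and pandas 2.3.3. A read with several perfect matches was divided equally between them, and sums per locus were rounded to whole numbers. Library size was the number of 18 to 26 nt reads that match the nuclear genome outside annotated rRNA, tRNA, snRNA and snoRNA, with no further scaling factor, and CPM stands for reads scaled to a common library size in the usual way. TMM was not the main scaling because many siRNA loci can move one way in ddm1-2. Reads equal to 1 of the 350 annotated mature miRNA sequences were counted as miRNAs and left out of the siRNA tables. siRNA tables hold 21 and 22 nt reads, or 23 and 24 nt reads, per annotated gene model.

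Transposable element (TE) gene models were the 3917 models that the annotation lists with the plain pseudogene biotype, which holds few element names. They were classed with BLAST+ 2.17.0: 35 by annotation or background knowledge, 1536 by translated similarity (tblastx, E-value up to 1e-10) and 1012 by nucleotide similarity (at least 80% identity over 100 bases) to a classed model. The classes hold 620 Athila, 642 copia, 445 CACTA, 411 LINE, 367 Mutator, 82 hAT and 16 Sadhu models, and 1334 models stayed unclassed. Near-identical copies share at least 95% identity over 200 bases. Classes are therefore those of the similarity search and not of a curated TE annotation. The Athila class grew from 1 seed locus and no other gypsy-type class had a seed, so it may hold other gypsy-type models.

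Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, filterByExpr, Benjamini-Hochberg, adjusted p threshold 0.05). The model for the 8 libraries in a naming series had a term per genotype and a term for the series, which left 2 residual degrees of freedom. Log2 differences are given ± a standard error worked back from the edgeR test statistic. With so few degrees of freedom, the spread of each locus leans on that of all loci, and very small p-values depend on this. The construct was compared with Col-0 in a model of all 9 libraries without a series term. rdr6-15, ddm1-2 rdr6-15 and the construct have 1 library each and were assumed to vary like the replicated groups. An interaction term tested whether the ddm1-2 effect differed between plants with RDR6 and rdr6-15 plants. An exact two-sided permutation test of 2 against 2 libraries cannot give a p under 0.33, so shares and totals carry no test. The filters left 5847 loci for 21-22 nt reads (2415 TE gene models), 8479 loci for 23-24 nt reads (3548 TE gene models) and 182 mature miRNAs, and in the construct model 2957, 5946 and 143.

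Groups of loci were the TE classes and 7 gene lists: TAS loci, PPR siRNA genes, ARF targets of TAS3, auxin receptor genes, NB-LRR genes, small RNA pathway genes, and known mobile or reactivated TEs. A further 4 lists of miRNAs covered triggers of secondary siRNAs, DCL4-dependent young miRNAs, miRNAs with TE targets and miRNAs of the small RNA pathway. Groups were tested with camera (limma 3.58.1, preset correlation 0.01, and with an estimated correlation beside it), and counts were also adjusted over the list alone. Named loci followed a rule: the 8 TAS loci, per comparison the 6 TE gene models with most 21-22 nt reads that rose and the 6 that fell, 4 and 4 for 23-24 nt reads, the 10 most abundant miRNA families, the listed miRNAs, and at most 4 members per list past the threshold. Samples, groups, tests, lists, naming rule and the alternatives below were fixed before the data were examined, except for choices described as made after seeing the data.

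Alternatives were a model without the series term, TMM factors, DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, all 18-26 nt reads as library size, uniquely matching reads only, 21 nt reads only, and each library of a replicated group left out in turn. Counting in 1 kb bins, and a library size without reads within 6 kb of an annotated 18S or 5.8S rRNA gene, were chosen after seeing the data. Tested on simulated data in which 100 loci were changed 8-fold, the 21-22 nt model recovered 29% of them for ddm1-2 against Col-0, 9% for each of the comparisons of ddm1-2 with its double mutants and 3% for the construct, and it recovered 0% of 3-fold changes. For 8-fold changes in the same order, with ddm1-2 dcl1-11 before ddm1-2 rdr6-15, the 23-24 nt model recovered 18%, 1%, 6% and 4% and the miRNA model 27.8%, 11.1%, 33.3% and 0%. The miRNA values rest on 18 changed miRNAs, or 14 for the construct. Smaller changes were mostly out of reach in the simulations, and a low count does not show that little changed. Most simulated loci were unchanged, which makes the adjusted threshold stricter than where many loci differ. Some differences under 3-fold, such as TAS1C in ddm1-2, did pass in the data. Shares carry 95% exact binomial (Clopper-Pearson) intervals from scipy 1.17.1. A fold against 0 reads is a lower bound computed from a floor of 3 reads over the group, and with 1 to 3 reads the ratio of pooled reads is given with its counting interval. Where a mutant lies in 1 naming series, these folds use the libraries of that series only, a choice made after seeing the data. Intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9.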

Results

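Small RNA was compared in inflorescences of Col-0 (2 libraries), ddm1-2 (2), ddm1-2 dcl1-11 (2), rdr6-15 (1), ddm1-2 rdr6-15 (1) and Col-0 with an AtGP1 miRNA construct (1). DDM1 is a chromatin remodeller that keeps transposable elements (TEs) silent, RDR6 is an RNA-dependent RNA polymerase, and DCL1 is the Dicer that makes miRNAs. Transcripts of DDM1, RDR6 and DCL1 were not measured, so loss of each function can only be checked indirectly. Genes and loci said below to rise or fall did so in their small RNA reads, not in transcripts. Reads of 21-22 nt from TAS loci, whose siRNAs need RDR6, came to 11801 and 10497 CPM in Col-0, 49.4 in rdr6-15 and 22.8 in ddm1-2 rdr6-15. Mature miRNAs took 3.03% and 3.48% of usable reads in ddm1-2 dcl1-11 against 2.83% in the ddm1-2 library of the same naming series, so no loss of miRNAs marks the weak dcl1-11 allele. The libraries fall into series A (Col-0 replicate 1, ddm1-2 replicate 1 and both rdr6-15 genotypes) and series B (Col-0 replicate 2, ddm1-2 replicate 2 and ddm1-2 dcl1-11), and pairs of values below are in the order A, B (replicate 1, replicate 2 for ddm1-2 dcl1-11). The series differ in composition: annotated rRNA, tRNA, snRNA and snoRNA took 2.29% to 3.42% of 18-26 nt reads in A, 22.6% to 39.4% in B and 40.9% in the construct library.

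In Col-0, TE reads were mostly 24 nt long, and 21 nt reads made up 4.38% and 6.79% of them. In ddm1-2, the 21 nt share of TE reads was 56.7% and 42.2%. It was 4.64% in rdr6-15 and 4.85% in ddm1-2 rdr6-15, but 41.8% and 39.6% in ddm1-2 dcl1-11. The construct library had a 21 nt share of 23.95%. Among all 18-26 nt reads, whether or not they match a TE, 21 nt reads made up 16.02% (95% CI 16-16.04) and 12.4% (12.35-12.42) in Col-0 and 29.3% and 13.8% in ddm1-2. These shares carry no test, since 2 libraries cannot be told from 2 others by permutation, and the intervals cover counting error only.

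**Figure D1:**
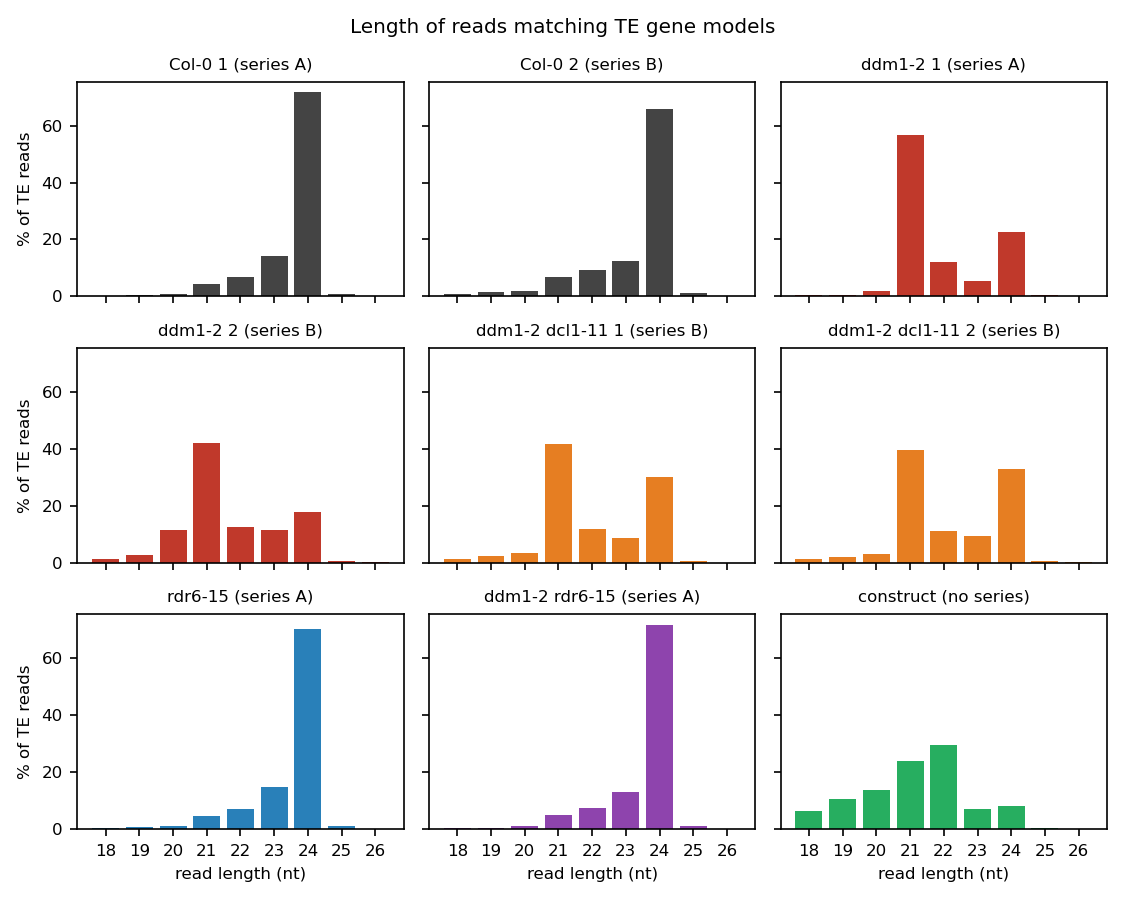
Lengths of reads from TE gene models in each library; the 21 nt share was 4.38% and 6.79% in Col-0, 56.7% and 42.2% in ddm1-2 and 4.85% in ddm1-2 rdr6-15.

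Loss of DDM1 raised 21-22 nt siRNAs most strongly at the Athila class. Athila elements are gypsy-type LTR retrotransposons, and the class may hold other gypsy-type models. Athila reads of this length were 2188 ± 1056 CPM in Col-0 (mean ± SD, n = 2) and 109935 ± 45759 in ddm1-2. This is 48.5-fold within series A and 53.8-fold within series B. All TE gene models together went from 9160 ± 1407 to 121363 ± 46588 CPM, or 15.2-fold and 10.8-fold. Athila thus made up most of the TE siRNAs of ddm1-2. CACTA transposons were 4.83-fold and 3.54-fold higher, and copia elements 1.67-fold and 2.54-fold. Mutator elements were at 0.393 and 1.01 of the Col-0 level. Of 2415 TE gene models tested, 499 rose and 485 fell (edgeR, adjusted p under 0.05), and 492 of the 499 and 444 of the 485 had the same sign in both series, from which they were called. Among Athila models 284 of 567 rose and 19 fell (305 and 23 when adjusted over the list alone), with a median log2 difference of 2.31. The camera test gave an adjusted p = 2.76e-33, but adjusted p = 0.67 with an estimated correlation. CACTA rose at 81 and fell at 36 of 286 models (89 and 47 over the list alone). Falls outnumbered rises for copia (53 rose and 91 fell of 398; 61 and 100 over the list alone), LINE (17 and 86 of 281; 21 and 91) and Mutator (6 and 67 of 190; 7 and 79). The same holds for unclassed models (54 and 176 of 639; 62 and 204) and hAT (3 and 9 of 47), while Sadhu had 1 and 1 of 7. With all gene models counted, 1472 of 5847 loci passed the test (660 higher and 812 lower). This split depends on scaling: TMM factors gave 507 higher and 347 lower, and DESeq2 size factors 545 and 1351. They moved the median of all loci by 0.30 and -0.55 log2. Leaving out a library of series A cut the TE falls (471 rose and 65 fell without Col-0 replicate 1, 470 and 82 without ddm1-2 replicate 1). Leaving out one of series B raised both counts (773 and 1017 without Col-0 replicate 2, 774 and 1019 without ddm1-2 replicate 2). The same holds for all loci, with 894 without Col-0 replicate 1 (668 higher and 226 lower), 938 without ddm1-2 replicate 1 (685 and 253), 2971 without Col-0 replicate 2 and 2970 without ddm1-2 replicate 2. Compared with the full fit, Mutator falls were fewer without a series A library and more without a series B library. The filter left 1167, 1124, 2802 and 2768 TE models to test in that order, so these counts are not of the same models.

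**Figure D2:**
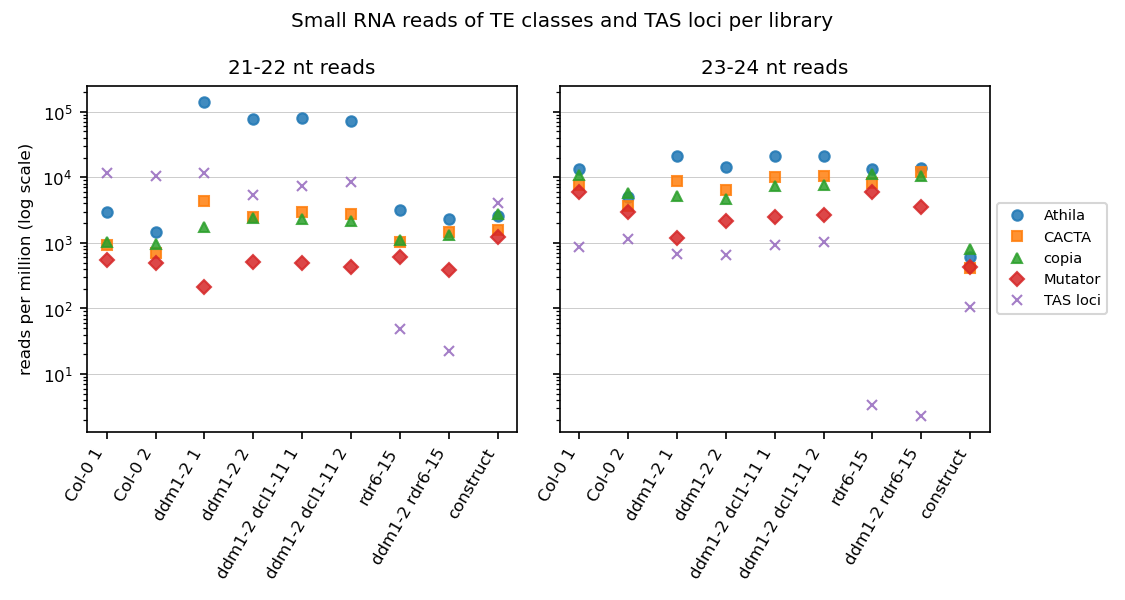
CPM of TE classes and TAS loci in each library, by read length; Athila 21-22 nt reads were 2188 ± 1056 in Col-0, 109935 ± 45759 in ddm1-2 and 2294 in ddm1-2 rdr6-15.

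The TE models with most 21-22 nt reads were Athila models on chromosomes 4 and 5, which have 8 to 25 near-identical copies. AT5G29975 (chromosome 5, 11323981-11329884) went from 38.8 and 19.3 CPM in Col-0 to 6408 and 4041 in ddm1-2, a log2 difference of 7.53 ± 0.27 (edgeR adjusted p = 1.24e-159). AT5G31719 rose by 7.79, AT5G32306 by 8.19, AT5G32107 by 7.45, AT4G06517 by 8.11 and AT5G32228 by 8.03 log2. EVD (AT5G17125, chromosome 5, 5630538-5634764), a copia element, rose from 1.16 and 0 to 101 and 372 CPM (log2 7.49 ± 0.52, edgeR adjusted p = 5.58e-44). The Mutator element ATMU1 (AT4G08680, chromosome 4, 5542431-5544862) went the other way, from 140 reads in Col-0 to 1 in ddm1-2, 149-fold lower (counting interval 26.4 to 5940; edgeR adjusted p = 2.42e-08). Of 8 known mobile or reactivated TEs tested, EVD rose and ATMU1 fell (1 and 7 when adjusted over the list alone). AT1G77095 fell by 1.30 ± 0.31 log2, and so did AT3G42645 (2.85), AT1G36775 (2.89), the CACTA model AT1G36790 (2.68), the LINE model AT5G40605 (2.67) and the copia model AT4G10990 (1.46). AT5G29975 kept its call in 16 of 16 settings, with log2 differences of 6.83 to 8.96.

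**Figure D3:**
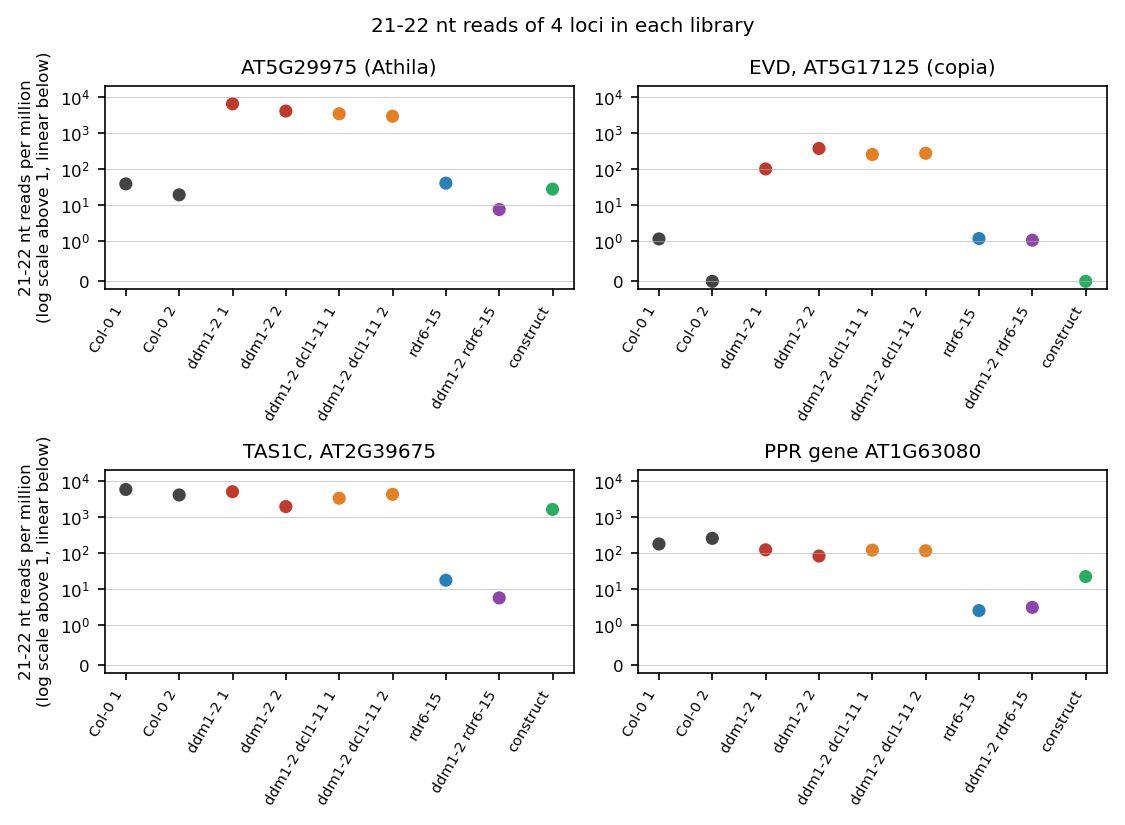
CPM of 21-22 nt at 4 loci in each library; AT5G29975 had 38.8 and 19.3 in Col-0, 6408 and 4041 in ddm1-2, and 7.56 in ddm1-2 rdr6-15.

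In ddm1-2, siRNAs of 23-24 nt fell at most of the TE models that changed. Mutator reads of this length were 5.01-fold lower in series A and 1.36-fold lower in B, and LINE and copia reads were at 0.395 and 0.479 of Col-0 in series A and at 0.704 and 0.806 in B. Athila totals went the other way, at 9188 ± 5820 CPM in Col-0 and 17861 ± 4581 in ddm1-2, 1.59-fold and 2.88-fold higher. CACTA (1.14-fold and 1.75-fold) and Sadhu (1.07-fold and 2.26-fold) totals were also above Col-0, and hAT totals were at 0.503 and 1.34. TE totals were at 0.81 and 1.18 of Col-0. Of 3548 TE models, 345 rose and 1322 fell (edgeR), and 344 of the 345 and 1280 of the 1322 had the same sign in both series, from which they were called. The rises included Athila (136 rose and 66 fell of 608; 128 and 65 over the list alone; camera adjusted p = 7.68e-13, but adjusted p = 0.91 with an estimated correlation). Falls led for Mutator (6 rose and 204 fell of 348; 6 and 228 over the list alone), copia (46 and 233 of 547; 51 and 247) and LINE (12 and 175 of 358; 13 and 184). They also led for CACTA (75 and 141 of 431; 83 and 155) and unclassed models (64 and 476 of 1173), and hAT (5 and 23 of 72; 5 and 23 over the list alone) and Sadhu models (1 and 4 of 11; 1 and 5). ATMU1 fell by 8.06 ± 0.87 log2 (edgeR adjusted p = 1.34e-17), from 99 and 51.5 CPM to 0.387 and 0. The ONSEN copia copy AT1G48710 went from 37.9 and 18.2 to 0.696 and 8.03 (log2 -3.59 ± 0.91, edgeR adjusted p = 0.000708), and the copies AT1G11265 and AT3G61330 fell by 3.29 and 3.37. In all, 7 of 8 known mobile or reactivated TEs fell (7 over the list alone), but 5 of these are ONSEN copies that share reads. The other ONSEN copies had 15.2 to 16.4 CPM in Col-0 and 10.3 to 11.5 in ddm1-2 in series B. AT5G29975 rose by 2.46 ± 0.47, AT2G06550 by 2.42, AT4G06477 by 2.12 and AT5G28535 by 2.06. AT1G36790 fell by 2.85 (but was at 2.82 above Col-0 with uniquely matching reads), AT3G42645 by 2.66, AT1G77095 by 1.36 and AT4G07031 by 1.10. Of 8479 loci, 3111 passed the test (775 higher and 2336 lower). TMM factors gave 1402 and 2212 and DESeq2 size factors 1348 and 2308, which moved the median of all loci by 0.51 and 0.42 log2. The count was 6787 without Col-0 replicate 2, 6772 without ddm1-2 replicate 2, 1573 without ddm1-2 dcl1-11 replicate 1 and 1578 without ddm1-2 dcl1-11 replicate 2. The TE split was 645 higher and 634 lower without Col-0 replicate 1 and 647 and 672 without ddm1-2 replicate 1.

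In ddm1-2, siRNAs fell at some PPR genes and at TAS1B and TAS1C, while most TAS loci did not pass the test. TAS1C (AT2G39675, chromosome 2, 16537288-16538277) went from 5789 and 4063 CPM in Col-0 to 5008 and 1937 in ddm1-2 (log2 -0.64 ± 0.19, edgeR adjusted p = 0.00607). TAS1B fell by 0.85 ± 0.29. Of 7 TAS loci tested, 2 fell and 0 rose (2 over the list alone), and TAS2 had 2620 and 3059 in Col-0 and 2924 and 1529 in ddm1-2. Of 8 PPR siRNA genes, 5 fell (7 over the list alone), among them AT1G63080 with 178 and 255 in Col-0 and 123 and 82.6 in ddm1-2 (log2 -1.07 ± 0.39, edgeR adjusted p = 0.0281). The PPR genes lie close together on chromosome 1, and a read matching several of them was split between them. Their counts moved together (estimated correlation 0.913), so their falls here and below are not separate results. The auxin receptor gene AFB3 fell by 1.82 ± 0.66 log2, the 1 fall among 4 auxin receptor genes (1 over the list alone). No NB-LRR gene (0 of 3; 1 fell over the list alone), small RNA pathway gene (0 of 4; 0 over the list alone) or ARF target of TAS3 (0 of 2; 0 over the list alone) passed the test. Camera gave the TAS list an adjusted p = 0.303 and the PPR list an adjusted p = 0.00617, but adjusted p = 0.806 for the PPR list with an estimated correlation. TAS1C kept its call in 7 of 16 settings and AT1G63080 in 10 of 16. Within the series, TAS totals in ddm1-2 were at 0.985 of Col-0 in A and at 0.506 in B.

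Without RDR6, the Athila siRNAs of ddm1-2 were back at the Col-0 level. Athila 21-22 nt reads were at 2294 CPM in ddm1-2 rdr6-15, 62-fold below ddm1-2 of series A and close to the 2934 of Col-0 in that series. All TE 21-22 nt reads were 12.6-fold lower, CACTA 3.06-fold and TAS loci 510-fold. AT5G29975 fell from 6408 to 7.56 CPM within series A (log2 -9.81 ± 0.42, edgeR adjusted p = 2.98e-115). AT5G31719, AT5G32306, AT5G32107, AT4G06517 and AT5G32228 fell by 10.41, 10.62, 10.12, 9.54 and 10.19. EVD fell to 1.07 CPM (log2 -7.02 ± 0.70, edgeR adjusted p = 7.85e-22). ATMU1 rose, with 232 reads against 1 in ddm1-2 of that series (229-fold, counting interval 40.7 to 9090; edgeR adjusted p = 7.72e-09). The TE models AT3G42645 (2.85 ± 0.55), AT5G35535 (2.50), AT1G36775 (2.26), AT1G36790 (2.12) and AT1G77095 (1.34) rose as well. AT3G43730 rose by 2.73, against -0.08 without ddm1-2 replicate 1, which leaves no ddm1-2 library in series A. Of 2415 TE models, 247 rose and 359 fell (edgeR). Athila fell at 256 and rose at 8 of 567 models (290 and 13 over the list alone; camera adjusted p = 1.29e-30, but adjusted p = 0.515 with an estimated correlation). Falls also led for CACTA (50 fell and 26 rose; 53 and 28 over the list alone). Rises led for copia (52 rose and 30 fell; 59 and 34 over the list alone), LINE (43 and 14), Mutator (24 and 2) and unclassed models (92 and 7). All 7 TAS loci fell (7 over the list alone), from TAS1B by 10.26 log2 to TAS3C by 5.03, and so did all 8 PPR siRNA genes (8 over the list alone), with AT1G63130 at least 490-fold lower. Both camera results for these lists had an adjusted p = 0.67 with an estimated correlation. In the other lists, AFB2 and AFB3 fell (2 of 4 auxin receptor genes; 2 over the list alone), and AT5G43740 fell (1 of 3 NB-LRR genes; 2 over the list alone). Among small RNA pathway genes, siRNA reads of AGO1 and DCL1 fell and those of the RDR6 locus rose (2 and 1 over the list alone). Reads of the RDR6 locus were at -1.38 log2 without ddm1-2 replicate 1. EVD fell and ATMU1 rose among known TEs (1 and 1 over the list alone), and no ARF target passed (1 fell over the list alone). Over all loci 949 passed (446 higher and 503 lower). TMM factors gave 202 and 352 and DESeq2 size factors 713 and 493, which moved the median by -0.19 and 0.41 log2. The count was 1427 without Col-0 replicate 1, 2426 without Col-0 replicate 2, 2424 without ddm1-2 replicate 2, 590 without ddm1-2 dcl1-11 replicate 1 and 592 without ddm1-2 dcl1-11 replicate 2. The ddm1-2 rdr6-15 group has 1 library, assumed to vary like the replicated groups. TE models rose and fell at 325 and 561 without Col-0 replicate 1, 734 and 685 without Col-0 replicate 2, 66 and 352 without ddm1-2 replicate 1, and 731 and 688 without ddm1-2 replicate 2.

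The effect of ddm1-2 differed between plants with and without RDR6. At Athila, ddm1-2 raised 21-22 nt reads 48.5-fold in the presence of RDR6, while the rdr6-15 library had 3161 CPM and ddm1-2 rdr6-15 had 2294. The interaction term was negative at 219 Athila models and positive at 3 of 567 (238 and 7 over the list alone; edgeR; camera adjusted p = 1.14e-38, but adjusted p = 0.41 with an estimated correlation). It was -9.96 ± 0.45 log2 at AT5G29975 (edgeR adjusted p = 1.81e-104), between -9.74 and -10.74 at the other 5 Athila models named above, and -7.64 ± 0.84 at EVD. It was positive at ATMU1 (7.33), AT3G42645 (3.34), AT1G36775 (3.25), AT1G36790 (3.03), AT5G35535 (2.07), AT3G43730 (2.00) and AT1G77095 (1.77). At AT3G43730 it was -0.12 without Col-0 replicate 1 and without ddm1-2 replicate 1. ARF4, a target of TAS3 siRNAs, had 4.67 ± 1.36 (1 of 2 ARF targets; 1 over the list alone). TAS1A and TAS1C had -1.60 and -0.98 (2 of 7 TAS loci; 2 over the list alone). Among known TEs, EVD was negative and ATMU1 positive (1 and 1 over the list alone), and 0 PPR, auxin receptor, NB-LRR or small RNA pathway genes passed (0 over each list alone). Of 5847 loci, 462 passed (182 higher and 280 lower), against 0 with TMM factors in edgeR (691 under an unadjusted p of 0.05). With these factors the edgeR log2 difference of AT5G29975 was -9.52 with a standard error of 3.24 and an adjusted p = 0.161. DESeq2 size factors gave 343 higher and 256 lower with the median moved by 0.53 log2, and the DESeq2 Wald test gave 81 and 213. The count was 718 without Col-0 replicate 1, 1622 without Col-0 replicate 2 (944 higher and 678 lower), 737 without ddm1-2 replicate 1, 1631 without ddm1-2 replicate 2 (951 and 680), 251 without ddm1-2 dcl1-11 replicate 1 and 262 without ddm1-2 dcl1-11 replicate 2.

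Among 23-24 nt reads, more TE models rose than fell with loss of RDR6 in ddm1-2. This direction turned without ddm1-2 replicate 1, which leaves no ddm1-2 library in series A to compare within the series. Mutator, LINE and copia reads of this length were 2.98-fold, 2.56-fold and 2.05-fold above ddm1-2 within series A, and Athila reads were at 0.648 of it. Of 3548 TE models, 598 rose and 77 fell (edgeR). Rises led for copia (140 rose and 5 fell), LINE (70 and 11), CACTA (67 and 3), Mutator (66 and 2) and unclassed models (201 and 11), while Athila had 42 rises and 44 falls. ATMU1 rose by 8.68 ± 0.95 log2 to 156 CPM (edgeR adjusted p = 7.16e-17). It was 1 of 6 rises among the 8 known TEs (6 over the list alone), of which 5 are ONSEN copies that share reads. These copies had 0.541 to 0.696 CPM in ddm1-2 of series A, against 30.2 to 35.1 in ddm1-2 without RDR6. In series B they had 8.03 to 11.5 in ddm1-2 and 23.6 to 28.4 in ddm1-2 dcl1-11. Only ddm1-2 replicate 1 was that low, so the ONSEN rises cannot be tied to loss of RDR6. AT3G43730 rose by 3.04, AT3G42645 by 2.76, AT5G35535 by 2.36 and AT1G36790 by 2.24 (-1.11 with uniquely matching reads), whereas AT5G29975 (-4.14 ± 0.70), AT3G43828 (-3.10), AT5G28535 (-2.79) and AT2G09187 (-2.20) fell. TAS loci fell at 6 (7 over the list alone) and PPR siRNA genes at 3 (5 over the list alone). The interaction was positive at 239 and negative at 49 TE models, but at 401 and 621 without ddm1-2 replicate 1, and negative terms also led without Col-0 replicate 1 (611 TE models). These include 69 copia, 37 LINE and 23 Mutator models with positive and 26 Athila models with negative terms. It was 8.69 ± 1.21 at ATMU1 (edgeR adjusted p = 9.81e-10; 1 of the known TEs, 6 over the list alone), 3.64 at AT1G36775, 3.21 at AT1G36790 (-1.90 with uniquely matching reads), 3.18 at AT3G42645 and 2.40 at AT3G43730. It was -4.60 at AT5G31719, -4.27 at AT5G29975, -3.26 at AT5G28535 and -2.57 at AT1G40101. Over all 8479 loci, 1285 passed against ddm1-2 (1044 higher and 241 lower). There were 1112 and 740 under TMM factors and 1076 and 764 under DESeq2 size factors (median moved by -0.55 and -0.60 log2). For the interaction 469 passed (380 and 89), with 559 and 276 under TMM factors and 541 and 294 under DESeq2 size factors (median moved by -0.32 and -0.39). Leaving out Col-0 replicate 1, Col-0 replicate 2, ddm1-2 replicate 1, ddm1-2 replicate 2, ddm1-2 dcl1-11 replicate 1 and ddm1-2 dcl1-11 replicate 2 in turn gave 4226, 5447, 1792, 5450, 345 and 346 against ddm1-2. In the same order, the interaction gave 1832, 4321, 1867, 4323, 51 and 52.

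In a DDM1 wild type, loss of RDR6 left TE siRNA totals close to Col-0 and removed most of the siRNAs of TAS loci and PPR genes. Within series A, TE reads of 21-22 nt in rdr6-15 were 1.06-fold those of Col-0, Athila reads 1.08-fold and TE reads of 23-24 nt 1.01-fold, while TAS reads of 21-22 nt were 239-fold lower. TAS1C fell to 17.7 CPM (log2 -8.59 ± 0.37, edgeR adjusted p = 3.06e-112). The log2 difference was -8.25 at TAS1A, -9.24 at TAS1B, -8.27 at TAS2, -6.56 at TAS3A, -7.80 at TAS3B and -3.84 at TAS3C, so 7 of 7 TAS loci fell (7 over the list alone). All 8 PPR siRNA genes fell (8 over the list alone), among them AT1G63080 by 6.41 log2 and AT1G62910 by 658-fold (3 reads left, counting interval 225 to 3190). AFB3 (2 reads left; 137-fold, counting interval 37.5 to 1140) and AFB2 (log2 -5.44) fell, 2 of 4 auxin receptor genes (2 over the list alone). ARF4 (2 reads left; 90.2-fold, 24.6 to 750; 1 of 2 ARF targets, 2 over the list alone) and the NB-LRR gene AT5G43740 (2 reads left; 113-fold, 31 to 941; 1 of 3, 2 over the list alone) fell. Reads of AGO1 (log2 -5.10) and DCL1 (3 reads left, 32.1-fold, 10.7 to 159) fell too. Small RNA reads of the RDR6 locus rose, with 84 reads against 2 in Col-0 of that series (40.1-fold, counting interval 10.8 to 336, edgeR adjusted p = 0.000429). Thus 1 small RNA pathway gene rose in its siRNA reads and 2 fell (1 and 2 over the list alone). The only TE model past the test was the CACTA model AT3G43828, with 18 CPM against 4.72 in Col-0 of series A (log2 1.69 ± 0.43, edgeR adjusted p = 0.0119). It was called in 5 of 16 settings, and no known TE passed (0 over the list alone). For 21-22 nt reads 68 loci passed in edgeR (8 higher and 60 lower). Among 23-24 nt reads 21 passed (7 and 14), including 5 TAS loci that fell (6 over the list alone), 0 PPR genes (8 fell over the list alone) and 0 TE models. Camera gave the TAS, PPR and auxin receptor lists an adjusted p = 5.29e-23, 4.33e-27 and 7.48e-08, but all had an adjusted p = 0.26 with an estimated correlation. The 7 TAS calls were lost with TMM factors (adjusted p = 0.0577 or more, and 0.287 at TAS1C, whose log2 difference was -8.12 or lower in all 16 settings). The rdr6-15 group has 1 library, assumed to vary like the replicated groups. In the order of left-out libraries used above, 405, 191, 173, 191, 42 and 43 loci passed for 21-22 nt reads and 1645, 719, 730, 727, 13 and 13 for 23-24 nt reads. Without Col-0 replicate 1, 103 TE models rose and 24 fell for 21-22 nt reads, and 747 and 56 for 23-24 nt reads. Leaving out the next 3 in turn gave TE rises of 14, 18 and 15 with 5 falls each, and for 23-24 nt reads 91 and 56, 104 and 59, and 93 and 57.

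With the weak dcl1-11 allele, the 21-22 nt TE siRNA totals of ddm1-2 stayed in place, while TE totals of 23-24 nt were 1.43-fold higher within series B. The total share of mature miRNAs was not lower either, so these values do not tell what loss of DCL1 function would do. Athila 21-22 nt reads were 80934 and 71429 CPM in ddm1-2 dcl1-11 against 77579 in the ddm1-2 library of the same series, a ratio of 0.982 from the mean, and TE reads had a ratio of 0.984. AT5G29975 had 3402 and 2906 against 4041, and EVD 253 and 274 against 372. Of 2415 TE models, 19 rose and 0 fell for 21-22 nt reads (edgeR), with 0 of 567 Athila models (0 over the list alone), 6 copia, 3 LINE, 1 CACTA, 0 Mutator and 9 unclassed models (15 over the list alone). AT3G42645 rose by 2.20 ± 0.50 log2 (edgeR adjusted p = 0.00408; called in 8 of 16 settings), AT2G05820 by 5.62, AT1G20390 by 4.10 and AT3G42922 by 3.72. Against the ddm1-2 library of the same series alone, AT2G05820 had 34 reads to 0 (at least 5.21-fold), AT1G20390 25 to 1 (11.5-fold, counting interval 1.88 to 472) and AT3G42922 25 to 3 (3.83-fold, 1.17 to 19.8). AT3G45253 and AT5G54203 also rose, with 14 and 17 reads to 0 in that series (at least 2.14-fold and 2.6-fold). With 21 nt reads only, AT3G45253 turned to -2.28 log2. TAS loci had 1.5 times the reads of ddm1-2 in that series, and 0 of 7 passed (1 rose and 1 fell over the list alone). TAS1C had a log2 difference of 0.73 (edgeR adjusted p = 0.085), and 0 known TEs, PPR, auxin receptor, NB-LRR, small RNA pathway or ARF genes passed (0 over each list alone). At 23-24 nt, 191 TE models rose and 8 fell, among them copia (46 rose and 1 fell; 65 and 1 over the list alone) and LINE (41 and 2; 65 and 2). Mutator had 15 rises and 0 falls, CACTA 14 and 0, Athila 3 and 0 and unclassed models 69 and 5. ATMU1 (6.38 ± 1.01, edgeR adjusted p = 1.1e-07; 29 reads against 0 within the series, at least 4.44-fold) and the ONSEN copy AT1G48710 (2.71; 23.6 and 24.9 CPM against 8.03 within the series and 0.696 in ddm1-2 of series A) rose, 2 of 8 known TEs (6 over the list alone), as did AT5G36935 (2.13), AT3G42645 (2.00), AT4G07502 (1.88) and AT3G43730 (1.65). AT2G10470 (-2.52) and AT5G55896 (-3.81) fell, and so did AT2G36040 (1 read against 40 in ddm1-2 of that series; 87.1-fold, 14.8 to 3520) and AT2G14793 (0 against 60; at least 43.5-fold). In all, 47 loci passed for 21-22 nt reads (35 higher and 12 lower), against 0 with TMM factors in edgeR (285 under an unadjusted p of 0.05) and 6 in DESeq2. DESeq2 size factors gave 11 and 30, all 18-26 nt reads as library size 64 and 9, and a library size without reads near rRNA genes 34 and 22. The median moved by -0.31 log2 with TMM factors and by -0.49, 0.31 and -0.14 with the other scalings. For 23-24 nt reads 359 passed (325 and 34). There were 205 and 118 with TMM factors and 235 and 112 with DESeq2 size factors (median moved by -0.91 and -0.81). In the order of left-out libraries used above, 228, 195, 259, 619, 4 and 3 loci passed for 21-22 nt reads (TE models 39 higher and 25 lower, 29 and 22, 42 and 34, 255 and 27, 0 and 0, and 0 and 0) and 1213, 1129, 1249, 2981, 19 and 47 for 23-24 nt reads.

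Of the mature miRNAs that passed the test in ddm1-2, miR5639-5p and miR843 rose most. miR5639-5p (chromosome 2, 10356784-10356804) had 0.445 and 0 CPM in Col-0 and 121 and 13.8 in ddm1-2 (log2 8.08, edgeR adjusted p = 1.17e-08). miR843 (chromosome 3, 17742147-17742167) had 17.9 and 2.93 against 1500 and 40.2 (log2 5.31 ± 0.86, edgeR adjusted p = 1.86e-07). Both were low in ddm1-2 rdr6-15, at 3.05 and 9.54 (log2 -5.32 and -6.85 against ddm1-2). miR5029 (3.21) and miR5639-3p (144 reads against 3; 45-fold, counting interval 15.1 to 221) also rose in ddm1-2, the latter on series A alone, with 0 reads in series B. So did miR780.2 (3.85), but on series B alone, with 14.9 and 18.9 CPM in Col-0 and ddm1-2 of series A and 0 and 269 in B. miR8183 fell by 4.89, miR841b by 2.98 (0 reads in series B), miR398b by 2.68 and miR166 by 1.09 ± 0.31 log2, the last from 24372 and 3458 to 10200 and 1834 (edgeR adjusted p = 0.0146). Abundant miRNAs that did not pass include miR159 with 15573 and 8999 in Col-0 and 9964 and 6346 in ddm1-2, miR167 with 18392 and 231 against 13220 and 278, and miR845a with 315 and 944 against 55.3 and 515 (log2 -1.69, edgeR adjusted p = 0.0881). In ddm1-2 dcl1-11, miR168 was at 336 and 423 against 97.6 in ddm1-2 of that series (log2 2.02 ± 0.45, edgeR adjusted p = 0.00106). With no series term this value turned to -2.85. miR8183 (7.13; 59 reads against 0 within the series, at least 9.04-fold) rose too, and so did miR5642 (3.50), but on replicate 2 alone (39.3 and 891 CPM against 55.1 in ddm1-2 of that series). In rdr6-15, miR867 (log2 2.88 ± 0.77, edgeR adjusted p = 0.0415) and miR780.2 (3.17) rose. The interaction was negative at miR780.2 (-6.25), miR780.1 (-5.99), miR867 (-5.81) and miR843 (-5.05) and positive at miR8183 (5.90). For miR780.1 and miR780.2 its size rests on series B, with 0 CPM in Col-0 and 534 and 269 in ddm1-2. Of the 14 triggers of secondary siRNAs and 4 DCL4-dependent young miRNAs, 0 passed in any comparison (0 over each list alone). The same is true of 3 miRNAs with TE targets, except that over the list alone 2 fell in ddm1-2 and 2 rose with the construct, and of 8 miRNAs of the small RNA pathway, except for miR168 in ddm1-2 dcl1-11 (1 over the list alone). Of 182 miRNAs tested, 9 passed in ddm1-2 (5 higher and 4 lower; 10 and 3 with DESeq2 size factors, which moved the median by 0.41 log2). There were 3 in ddm1-2 dcl1-11 (3 and 0), 4 in ddm1-2 rdr6-15 (1 and 3), 2 in rdr6-15 (2 and 0) and 5 for the interaction (1 and 4). With no series term these counts were 0 (5, 4, 3, 1 and 1 under an unadjusted p of 0.05 in edgeR, and 6, 2, 2, 0 and 2 calls in DESeq2 with the term), and miR166 lost its call (adjusted p = 0.999). Without Col-0 replicate 2 they were 36, 15, 20, 19 and 19, and without ddm1-2 replicate 2 they were 36, 12, 23, 17 and 20. The counts were 10, 5, 5, 9 and 12 without Col-0 replicate 1, and 10, 7, 8, 0 and 12 without ddm1-2 replicate 1. Without ddm1-2 dcl1-11 replicate 1 they were 5, 3, 2, 0 and 2, and without ddm1-2 dcl1-11 replicate 2 they were 5, 2, 1, 0 and 1.

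The construct library stood apart by a high level of miR845a, low levels of 24 nt siRNAs and low levels of some other miRNAs. miR166 was at 61.2 CPM against 24400 and 3460 in Col-0, and miR167, miR319 and miR390 had 2, 1 and 1 reads. miR167 was also low in Col-0 of series B. miR845a had 27606 CPM against 315 and 944 in Col-0 (log2 5.46 ± 1.65, edgeR adjusted p = 0.136). TE reads of 23-24 nt were at 4116 CPM against 77916 and 39779 in Col-0, and TE reads of 21-22 nt at 14376 against 10154 and 8165. Protein-coding genes had 62366 CPM of 21-22 nt against 18170 and 29471, and 8.9% of the deposited reads of this library were 18-26 nt long. Of 1359 TE models, 35 rose and 5 fell for 21-22 nt reads (edgeR), with 20 of 188 LINE (20 over the list alone), 7 of 198 copia (4 over the list alone), 3 Mutator and 2 of 414 Athila models rising (0 over the list alone). The copia models AT3G29525 (8.28 and 3.51 in Col-0, 228 here; log2 5.21 ± 1.22, edgeR adjusted p = 0.02) and AT3G29540 (5.12) and the LINE model AT2G01029 (4.64) led the rises, followed by AT3G29615 (3.20), AT5G29075 (3.17) and AT2G01037 (3.16). AT1G77095 fell from 374 and 624 to 11.1 (2 reads; 36.6-fold, counting interval 10.1 to 302; edgeR adjusted p = 0.00643). AT3G42645, AT1G36790, AT1G36775 and AT4G07031 had 0 reads (at least 6.19-fold, 4.98-fold, 4.71-fold and 3.62-fold lower). Folds in this paragraph that rest on 0 to 3 reads pool both Col-0 libraries, most of whose reads are from replicate 1. Against replicate 2 alone they would be smaller for TAS3B (306 and 169 CPM in Col-0), for ATMU1 at 23-24 nt (99 and 51.5) and for miR159. For AT1G77095 at 21-22 nt the fold would be larger. TAS3A was left with 1 read (146-fold lower, 26.3 to 5790; edgeR adjusted p = 0.00439) and TAS3B with 0 (at least 17.2-fold lower), 2 of 7 TAS loci (3 over the list alone). PPR genes passed at 0 (3 fell over the list alone), as did small RNA pathway genes and the ARF target tested (0 over each list alone). Among 23-24 nt reads 0 TE models rose and 249 fell. AT1G77095 was at least 137-fold lower, AT3G43730 at least 68-fold, AT4G07031 at least 45.4-fold, AT1G36790 at least 26.1-fold and ATMU1 at least 5.55-fold. Of 6 TAS loci 4 fell (5 over the list alone) and of the known TEs 1 (5 over the list alone). Of 143 miRNAs, 0 passed in edgeR (29 under an unadjusted p of 0.05; 27 in DESeq2), also among 12 triggers of secondary siRNAs (0 over the list alone), while 2 of 3 miRNAs with TE targets rose over the list alone. miR159 had 3 reads (880-fold lower, counting interval 301 to 4270, edgeR adjusted p = 0.12). In all, 288 loci passed for 21-22 nt reads (228 higher and 60 lower) and 811 for 23-24 nt reads (187 and 624). TMM factors gave 142 and 139 and, for TE models, 0 and 21, with the median of all loci moved by -1.91 log2. DESeq2 size factors gave 172 and 73 (median moved by -0.66). For 23-24 nt reads these gave 125 and 149 (0.16) and 133 and 1 (0.10). For 23-24 nt reads, all 18-26 nt reads as library size gave 124 and 146, and a library size without reads near rRNA genes 147 and 128. For 23-24 nt reads, 265 passed without Col-0 replicate 1, 1524 without Col-0 replicate 2, 303 without ddm1-2 dcl1-11 replicate 1 and 302 without ddm1-2 dcl1-11 replicate 2, while 19 miRNAs passed without ddm1-2 replicate 2. In this single library, assumed to vary like the replicated groups, 51.7% of the usable reads lay near rRNA genes.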

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

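The tests of RDR6-dependent production and of dilution in the construct library were chosen after the result was seen; the other tests in this part were planned before.

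The effect of ddm1-2 differed with and without rdr6-15 by the interaction test at 462 loci for 21-22 nt reads, 469 loci for 23-24 nt reads and 5 mature miRNAs. These counts are flagged as a difference between groups, and ddm1-2 rdr6-15 and rdr6-15 each rest on 1 library. Reads outside the lengths compared were flagged as data the comparisons do not use, above the level of Col-0 in series B. Reads of 15-17 nt took 16% of deposited reads in ddm1-2 dcl1-11 replicate 1, 14.7% in its replicate 2, 25.9% in ddm1-2 replicate 2 and 29.4% in the construct library, against 8.55% in Col-0 replicate 2. Reads of 27-34 nt that match tRNA took 3.18% in ddm1-2 replicate 2, 7.55% in ddm1-2 dcl1-11 replicate 2 and 26.9% in the construct library, against 2.5% in Col-0 replicate 2. In ddm1-2 dcl1-11 replicate 1 the value was 2.51%, near that of Col-0. The files of series A hold only 18-26 nt reads, so they offer no comparison for these lengths.

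21-22 nt reads of Athila loci were higher in ddm1-2, and 4 explanations were weighed. Reads shared between near-identical copies cannot be the whole cause, since 151 Athila loci were still higher with uniquely matching reads only, although fewer loci hold such reads. For breakdown fragments without a fixed length, the share of 21 and 22 nt among Athila reads was 2.83 times that among protein-coding reads in the lower of the ddm1-2 libraries. Protein-coding reads there are mostly 23-24 nt (58401 and 56739 CPM, against 14297 and 30175 of 21-22 nt), so this ratio alone cannot exclude breakdown. Athila reads of 21 nt were at 120130 and 63143 CPM in ddm1-2, against 22161 and 14435 of 22 nt. Such a peak at 1 length argues against fragments without a fixed length. Scaling is excluded, with the median Athila log2 difference 2.28 above that of loci outside TE gene models. For RDR6-dependent production, 219 Athila loci were lower and 3 higher in the interaction test, but that result prompted the explanation and cannot test it. Within series A, Athila reads of 21-22 nt were at 142291 CPM in ddm1-2, 2294 in ddm1-2 without RDR6 and 2934 in Col-0. The rise in ddm1-2 was therefore not seen without RDR6, in the 1 library that lacks both functions. How RDR6 brings this about was not tested and stays open.

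Mature miRNAs differ between the naming series in Col-0 as in ddm1-2. Dilution by rRNA and other breakdown fragments would move all miRNAs alike, but the 10th to 90th percentile span of the log2 difference was 5.60 in the narrower genotype. Counting noise at lower depth is excluded, since the series differences of Col-0 and ddm1-2 correlate at 0.76 over 182 miRNAs. A difference in kit or ligation between the series remains open, because the labels do not say which library came from which kit. No biological explanation was tested, as the labels give no difference between the series.

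The construct library had few 24 nt reads. Dilution by breakdown fragments would lower miRNAs and 24 nt siRNAs alike, but there were 0.0897 TE reads of 23-24 nt per mature miRNA read, against 0.609 and 1.12 in Col-0. Without miR845a, the most abundant miRNA there, this value is 0.225 against 0.611 and 1.15, so part of the gap comes from miR845a. Without miR845a the value misses the limit set for excluding dilution, so dilution is not excluded. Loss of 23 and 24 nt molecules by size was tested on structural RNA. Structural RNA had 0.822 reads of 23-24 nt per read of 21-22 nt, against 1.08 and 1.3 in Col-0. This met the limit set for excluding such a loss, but it assumes structural fragments of the same lengths in each library. TAS reads of 23-24 nt were at 105.8 CPM against 864.2 and 1131 in Col-0, and those of 21-22 nt at 4087 against 11801 and 10497. Loss by size is therefore not excluded. A change brought by the construct itself cannot be told from a property of this single library.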

How the results depend on the processing

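Counting in 1 kb bins and the library size without reads near rRNA genes were chosen after the result was seen. No paired analysis was possible because the labels give no replicate numbers, so the series term of the model is the only block. A left-out library leaves its group with 1 sample, assumed to vary like the others. In the model with a series term it also leaves only 1 residual degree of freedom. Where its genotype is found in both series, the residual spread comes only from the replicated double mutant. Where it is of that double mutant, the spread comes only from how far the ddm1 effect differs between the series. Counts of calls with a library left out thus rest on different estimates of spread. Depth limits series B and the construct, which have 179599 to 1707822 usable reads. Over the 20 results that answer the comparisons, 92 values under other settings stayed within 1.5 times the main value and 67 moved; with a library left out, 24 stayed and 84 moved. Of the 24 counts of TE gene models, 106 values stayed and 98 moved under other settings, and 35 stayed and 109 moved with a library left out. For named loci and miRNAs, 2248 values under other settings kept direction and side of the threshold, 277 were weaker, 22 stronger and 5 reversed. With a library left out, 1672 were kept, 183 weaker, 62 stronger and 9 reversed. Apart from fewer reads (unique reads, 21 nt only) and other units (bins), the cause was not tested. Under TMM factors the median standard error of the 21-22 nt interaction was 1.88 log2, against 1.61 in the main fit. Whether this explains the loss of calls there was not tested.

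21-22 nt loci, ddm1-2 against Col-0: 1472 in the report, 825 with no series term, 854 with TMM factors, 820 with DESeq2, 779 with unique reads, 6032 in 1 kb bins and 894 to 2971 with a library left out. ddm1-2 dcl1-11 against ddm1-2: 47, then 0 with TMM factors (6 with DESeq2), 22 with no filter, 73 with all 18-26 nt reads, 11 with unique reads, 15 with 21 nt only, 161 in bins and 3 to 619 with a library left out. ddm1-2 rdr6-15 against ddm1-2: 949, then 601 with no series term, 554 with TMM factors, 499 with DESeq2, 515 with unique reads, 3250 in bins and 590 to 2426 with a library left out. rdr6-15 against Col-0: 68, then 33 with TMM factors, 38 with DESeq2, 39 with unique reads, 130 in bins and 42 to 405 with a library left out. Interaction: 462, then 289 with no series term, 0 with TMM factors (294 with DESeq2), 181 with unique reads, 1731 in bins and 251 to 1631 with a library left out. Construct: 288, then 156 with 21 nt only and 240 to 400 with a library left out.

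24 nt loci (23-24 nt), ddm1-2 against Col-0: 3111, then 15856 in bins and 1573 to 6787 with a library left out. ddm1-2 dcl1-11 against ddm1-2: 359, then 151 with DESeq2, 227 with no filter, 829 with all 18-26 nt reads, 196 with unique reads, 1730 in bins and 19 to 2981 with a library left out. ddm1-2 rdr6-15 against ddm1-2: 1285, then 5756 in bins and 345 to 5450 with a library left out. rdr6-15 against Col-0: 21, then 37 with TMM factors, 37 with DESeq2 size factors, 123 in bins and 13 to 1645 with a library left out. Interaction: 469, then 254 with no series term, 835 with TMM factors, 835 with DESeq2 size factors, 289 with no filter, 810 with all 18-26 nt reads, 253 with unique reads, 2613 in bins and 51 to 4323 with a library left out. Construct: 811, then 274 with TMM factors, 134 with DESeq2 size factors, 276 with DESeq2, 456 with no filter, 270 with all 18-26 nt reads, 275 without reads near rRNA genes, 446 with unique reads and 265 to 1524 with a library left out.

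Mature miRNAs, ddm1-2 against Col-0: 9, then 0 with no series term, 22 with all 18-26 nt reads and 5 to 36 with a library left out. ddm1-2 dcl1-11 against ddm1-2: 3, then 0 with no series term, 5 with DESeq2 size factors, 5 without reads near rRNA genes and 2 to 15 with a library left out. ddm1-2 rdr6-15 against ddm1-2: 4, then 0 with no series term, 2 with DESeq2 and 1 to 23 with a library left out. rdr6-15 against Col-0: 2, then 0 with no series term, TMM factors, DESeq2 size factors or DESeq2, and 0 to 19 with a library left out. Interaction: 5, then 0 with no series term, 3 with TMM factors, 2 with DESeq2 and 1 to 20 with a library left out. Construct: 0, then 27 with DESeq2 and 0 to 19 with a library left out. For 21-22 nt loci, the 34 camera calls of TE classes and lists dropped to 0 with an estimated correlation. The mean 21 nt share of the ddm1-2 libraries (29.3% and 13.8%) was 21.6%, against 13.4% of distinct sequences and 23.9% of reads that match the genome. Both lie within 1 SD, but that SD is the gap between 1 library of each series, so it does not show that the share is stable. No library was left out of it.

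Reversed log2 differences with a library left out were, in ddm1-2 against Col-0, TAS3A (-1.04 to 0.73; reversed at 0.73 without Col-0 replicate 2 and without ddm1-2 replicate 2) and TAS3C (-0.93 to 1.32; reversed at -0.93 without Col-0 replicate 1 and without ddm1-2 replicate 1). In ddm1-2 dcl1-11 against ddm1-2, miR839 ran from -1.53 to 8.60, the latter without ddm1-2 replicate 2. In ddm1-2 rdr6-15 against ddm1-2, AT3G43730 ran from -0.08 to 4.10 and RDR6 from -1.38 to 4.66. Both were reversed without ddm1-2 replicate 1, which leaves no ddm1-2 library in series A. The AT3G43730 interaction ran from -0.12 to 4.06, reversed without Col-0 replicate 1 and without ddm1-2 replicate 1. With unique reads AT1G36790 (24 nt) was reversed to 2.82 in ddm1-2 against Col-0, to -1.11 in ddm1-2 rdr6-15 against ddm1-2 and to -1.90 in the interaction. In ddm1-2 dcl1-11 against ddm1-2, AT3G45253 was at -2.28 with 21 nt reads only and miR168 at -2.85 with no series term.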

Other observations

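The counts of shared loci and the 5' nucleotides below were chosen after the ddm1-2 result was seen, and the test of miRNA sites was planned before.

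TE reads of 21 nt began with U in 30.4% and 30.4% of cases in Col-0 and in 38.4% and 37% in ddm1-2, and TE reads of 22 nt in 34.7% and 29.2% against 48.5% and 44.6%. In ddm1-2 rdr6-15 the values were 32% and 34%, near those of Col-0 in series A, and in ddm1-2 dcl1-11 35.7% and 36.2% of 21 nt reads began with U. The construct library had 19.4% for 21 nt reads. TE reads of 24 nt began with A in 54.5% to 59.1% of cases in all libraries. Athila reads of 21 nt came from the sense strand in 55.6% and 48.3% of cases in ddm1-2, and CACTA reads of 21 nt in 65.9% and 64.2%, against 53.4% and 59.7% in Col-0. These shares carry no test.

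Of the 499 TE models with higher 21-22 nt reads in ddm1-2, 324 were lower in ddm1-2 rdr6-15 than in ddm1-2 (64.9%; 74.2 for independent lists). In 20 simulations of unchanged groups the overlap was 0, for these and all lists below, which is chance with no effect and leaves out the real effects of ddm1-2. Of the 485 lower models, 179 were higher in ddm1-2 rdr6-15 (36.9%, 49.6 for independent lists) and 19 in ddm1-2 dcl1-11 (3.82 for independent lists). For the 499 higher models no overlap with falls in ddm1-2 dcl1-11 was possible, since 0 TE models fell there. For 23-24 nt reads, 563 of 1322 lower models were higher in ddm1-2 rdr6-15 (42.6%; 223 for independent lists) and 188 in ddm1-2 dcl1-11 (14.2%; 71.2). Part of the excess may come from the shared ddm1-2 libraries.

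A hypothesis is that TE gene models with a predicted miRNA site gain 21-22 nt reads in ddm1-2 more often than others. Sites for 91 miRNAs were found in 30 of 2415 TE models, and 4 of the 30 (13.3%) were called higher, against 20.8% of models without a site. Within classes, 28.4% of 10000 permutations of the site label gave a lower count (median 5, one-sided permutation p = 0.7), and 8 of 20 sets of shuffled miRNAs gave a lower count. Only 2 of 567 Athila models had a site and neither was called higher, so the search was too sparse to tell. The data therefore give no sign for the hypothesis and do not exclude it, since sites outside the annotated models or with weaker pairing were not searched.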
